A study of Rattus norvegicus with 9 samples.

How the data were processed

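RNA from HBZY-1 cells, an established line of rat glomerular mesangial cells (the contractile support cells of the kidney's filtering tuft), was sequenced in 9 libraries. The labels place 3 libraries in each of 3 groups: control, an LPS-induced model, and cells given a high dose of a water extract of freeze-dried Poecilobdella manillensis, a blood-feeding leech. The control label does not say whether those cells were untreated. LPS, lipopolysaccharide, is a component of the bacterial outer membrane that is widely used to provoke inflammatory responses in culture. The labels do not state whether the extract group also received LPS, and give no dose or exposure time, so the third group is called the extract group throughout. The series describes the replicates as biological, without saying whether they were cultured on separate days.

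Gene and transcript abundances were deposited by the authors as TPM (each transcript's share of all transcripts in a library, scaled to a total of 1000000), rounded to 2 decimals, in 1 table of 30560 genes and 1 of 54991 transcripts. The submitters' processing notes name fastp, HISAT2 2.1.0 and RSEM 1.3.3, without their roles or settings. The genome build and annotation are not given in the sources used here, nor is the strandedness of the libraries. TPM is a relative unit: each library sums to 1000000 by construction, so a few strongly raised abundant genes lower the TPM of all others. TPM keeps no record of sequencing depth, so the depth of each library is unknown and no counting interval or detection floor is given. Precision therefore rests on the spread between the 3 libraries of a group. In the tests this spread was pooled over the 3 groups and moderated across genes.

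Both tables carry Ensembl rat identifiers and do not pair them with gene names. The reference table supplied for this work, 47357 rat genes of the assembly GRCr8, holds no Ensembl identifier, and 0 identifiers matched. Names were therefore not assigned, and the 25 gene lists and the genes chosen by name were not analysed here, including those of the TXNIP/NLRP3 pathway named in the title of the series. These lists, the comparisons, the tests and most alternatives had been fixed before the data were examined. The rule for named genes had excluded bare identifiers. In its place the identifier with the smallest p in each direction of LPS versus control and of extract versus LPS, with no overlap between the groups' values, was reported, which is a choice made after the values were seen.

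The libraries were assigned to columns by the code that opens each library's title. Genes with a mean of at least 1 TPM over the 9 libraries were tested, 12192 in all. Values were taken as log2(TPM + 1), and a fold change on this scale understates the change of genes with low TPM. One linear model with a mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (moderated tests with a mean-variance trend, two-sided, 6 residual degrees of freedom). The p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes with an adjusted p below 0.05 are called changed. The same test was run on transcripts with a mean of at least 1 TPM. Among the tested genes, 53 (0.43%) had values identical to those of another gene in every library, as near-identical copies would, and each was counted as a gene.

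The procedure was tested on simulated data made from the means and spreads of the 12192 genes with known changes in LPS versus control. It recovered 71.6% of 67 genes changed by 0.5 on the log2 scale, 92.5% of 67 changed by 1 and 95.5% of 66 changed by 2, with 11 false calls among 184.

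The counts of genes in which one group stood apart, the follow-up of strongly changed genes, the transcript shares and the measures described next were chosen after the gene-level values were seen. The typical log2 difference between 2 groups is the root mean square fold change over the tested genes, after subtraction of the variance expected from the replicate spread. The slope of the extract-control changes on the LPS-control changes was corrected in the same way for the control libraries that both share. Their standard errors come from a jackknife over the libraries. Transcripts were linked to genes where consecutive transcript TPM values summed to the gene's TPM in all 9 libraries within 0.006 TPM per rounded value, which held for all 12192 tested genes. A transcript's share is its TPM as a percent of its gene's TPM. Shares were tested with limma, without a trend, for genes of at least 5 TPM and transcripts with a mean share of 10% to 90%.

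The alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, rescaling of the libraries by the median of ratios, quantile normalization, the replicate number as a block, fits of only the 2 groups compared, no mean-variance trend, library weights, a fold threshold, and leaving out each library in turn. The replicate numbers were not taken to pair the libraries, because the labels do not say what a number shares. Deviations of same-numbered libraries from their group means correlated between -0.055 and 0.095 over the genes, and those of differently numbered libraries of different groups between -0.11 and 0.089.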

Results

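The transcriptomes of 9 HBZY-1 libraries were compared, 3 from control cells, 3 from the LPS-induced model and 3 from cells given the leech extract. The series asks whether the extract lessens inflammatory injury of mesangial cells. Between 15479 and 15837 genes had a TPM above 0 in a library, and between 11954 and 12104 reached 1 TPM. Libraries of one group correlated at 0.9766 or more over the tested genes (Pearson's r on the log2 scale, across genes), and libraries of different groups at 0.9689 or less. The median coefficient of variation between the 3 libraries of a group was 5.17% in control, 5.8% in LPS and 4.67% in extract cells. The first 2 principal components held 34.5% and 26.99% of the variance. On the first, the extract libraries lay between 28.4 and 32.05, the control libraries between -7.97 and -5.51, and the LPS libraries between -27.55 and -21.37. On the second, the control libraries lay between 25.45 and 29.8 and the other 6 between -22.09 and -7.49.

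LPS versus control addressed how the LPS-induced model differed from control cells. In all 3 comparisons the p-values measure differences against the spread between libraries of a group. A difference in culture or processing between groups would therefore also be called a change. Of 12192 genes tested, 1193 were higher and 3769 lower in the LPS libraries (limma, adjusted p below 0.05). Most changes were small: the median log2 fold change was 0.33 among the genes that were higher and -0.30 among those that were lower, against a median standard error of 0.064. At least 2-fold changes were found for 157 genes that were higher and 151 that were lower. The strongest responses were mainly increases, with 27 genes at least 8-fold higher and 3 at least 8-fold lower, of which 2 had identical values in every library. In the whole table, 4 genes were listed at 0 TPM in all 3 control libraries and at 1 TPM or more in all 3 LPS libraries, and 1 gene showed the opposite. The excess of lower genes depended on the scaling of the libraries. Lower genes made up 76% of those called with TPM as deposited and 52% after rescaling by the median of ratios, which called 2102 higher and 2278 lower. All 157 genes that were at least 2-fold higher, and 148 of the 151 that were at least 2-fold lower, were called in the same direction after rescaling. The 10 most abundant genes of each library took 12.2% to 12.6% of the TPM in control, 14.2% to 14.7% in LPS and 13.3% to 13.9% in extract libraries. Values did not overlap between LPS and control libraries for 50.1% of genes, where chance gives 10%.

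The gene with the smallest p among those higher with LPS, ENSRNOG00000046834, was nearly silent in control cells at 0.147 ± 0.038 TPM (SD, n = 3). It reached 98.8 ± 3.8 TPM in LPS cells and stood at 40.6 ± 2.6 TPM in extract cells. Its log2 fold change was 6.44 ± 0.056 (SE) in LPS versus control (limma adjusted p = 6.66e-12) and -1.26 ± 0.056 in extract versus LPS (limma adjusted p = 1.44e-07). With a control level this low, the size of the LPS-control change depended on the pseudocount, from 4.33 with a pseudocount of 5 to 8.66 with 0.1. Among the genes that were lower with LPS, ENSRNOG00000010248 had the smallest p. It fell from 132.3 ± 2.0 TPM in control to 32.8 ± 1.7 TPM in LPS cells, a log2 fold change of -1.98 ± 0.041 (limma adjusted p = 2.09e-09). At 31.8 ± 0.63 TPM in extract cells it did not differ detectably from LPS cells, with a log2 fold change of -0.04 ± 0.041 (limma adjusted p = 0.399).

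**Figure D1:**
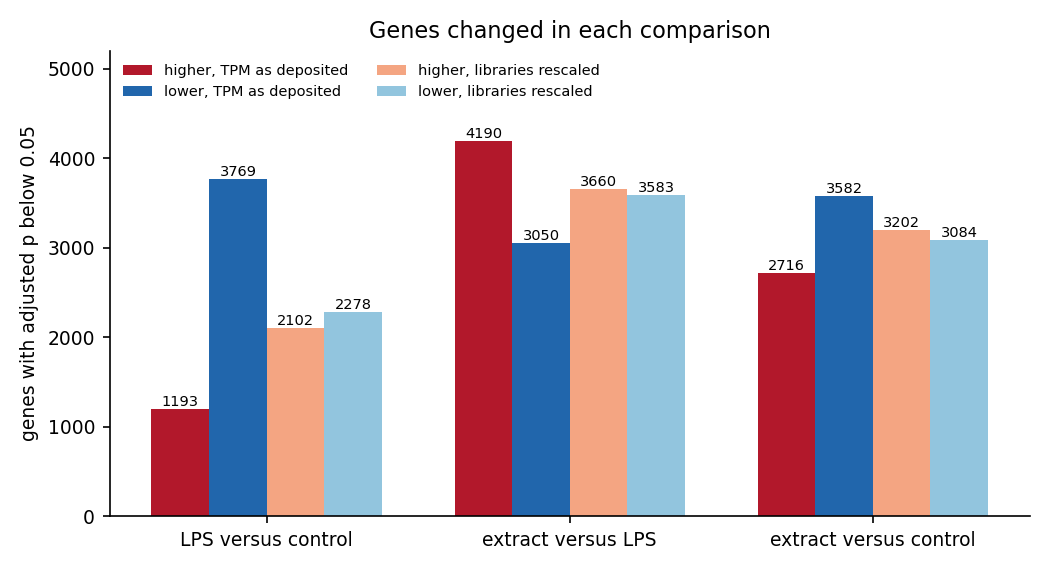
Number of genes with an adjusted p below 0.05 (vertical axis) that were higher or lower in each of the 3 comparisons (horizontal axis), with TPM as deposited (dark bars) and after rescaling of the libraries by the median of ratios (light bars). With LPS versus control, 1193 higher and 3769 lower genes became 2102 and 2278 after rescaling.

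Extract versus LPS addressed how cells given the extract differed from the inflammatory model. Among the 3 comparisons it gave the highest number of changed genes, with 4190 genes higher and 3050 lower in the extract libraries. At least 2-fold changes were found for 303 genes that were higher and 250 that were lower, and at least 8-fold changes for 7 and 13 genes. The median log2 fold change was 0.38 among the genes that were higher and -0.36 among those that were lower. Values did not overlap between the 2 groups for 65.1% of genes. After rescaling, 3660 genes were higher and 3583 lower.

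ENSRNOG00000002331 had the smallest p among the genes higher in extract than in LPS cells. It stood at 15.1 ± 0.46 TPM in control, 12.8 ± 0.65 TPM in LPS and 203.3 ± 3.5 TPM in extract cells (SD, n = 3). Its log2 fold change was 3.89 ± 0.043 (SE) against LPS cells (limma adjusted p = 6.67e-11) and 3.67 ± 0.043 against control cells (limma adjusted p = 5.67e-11). Its small difference between LPS and control, -0.22 ± 0.043 (limma adjusted p = 0.00339), did not pass the threshold after rescaling (limma adjusted p = 0.0643). ENSRNOG00000014320, the gene with the smallest p among those lower in extract than in LPS cells, rose from 486.1 ± 11.3 TPM in control to 985.6 ± 22.0 TPM in LPS cells. In extract cells it stood at 246.1 ± 12.5 TPM, below both other groups. Its log2 fold change was 1.02 ± 0.040 in LPS versus control (limma adjusted p = 1.33e-07), -1.998 ± 0.040 in extract versus LPS (limma adjusted p = 2.83e-09) and -0.98 ± 0.040 in extract versus control (limma adjusted p = 1.28e-07).

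**Figure D2:**
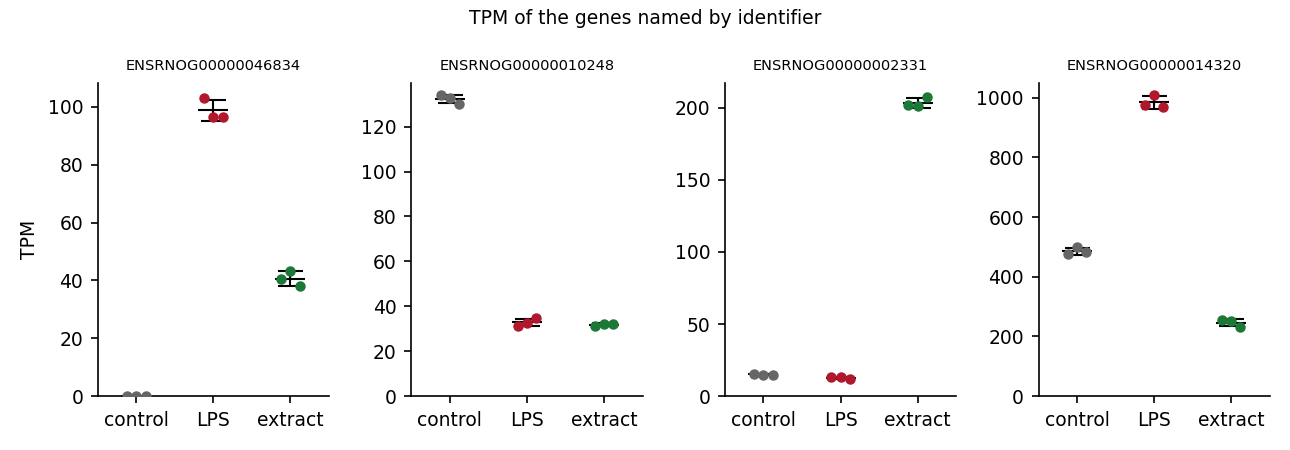
TPM (vertical axes, each from 0) of the genes named by identifier in control, LPS and extract libraries. Points are the 3 libraries of a group, and bars give the mean and SD; ENSRNOG00000002331 stood at 203.3 TPM in extract cells and at 15.1 and 12.8 TPM in control and LPS cells.

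The genes changed by LPS were followed into the extract group. Of the 1193 genes higher with LPS, 808 were lower in extract than in LPS cells, 119 were higher still and 266 did not pass the threshold. Of the 3769 genes lower with LPS, 2518 were higher in extract than in LPS cells, 387 were lower still and 864 did not pass. In total 3326 genes changed with LPS and changed the opposite way in extract versus LPS. Many of them went past control. Of the 808 genes, 377 were below control in extract cells, 287 did not differ from it past the threshold and 144 were still above. Of the 2518 genes, 1064 were above control, 1182 did not differ from it and 272 were still below. After rescaling, 1419 of 2102 genes higher with LPS were lower in extract than in LPS cells, and 651 of the 1419 were below control. Likewise 1579 of 2278 genes lower with LPS were higher, 780 of them above control. LPS versus control and extract versus LPS share the LPS libraries, whose chance values push the fold changes apart. In 100 simulations of unchanged groups the correlation of the fold changes across genes was -0.495, close to the observed -0.507, and opposite signs made up 66.7% of genes against 69.8% observed. The covariance, to which the shared libraries add an equal amount with or without effects, was -0.112 against a simulated -0.0236 (range -0.0322 to -0.0153). The simulated groups had no effects, and groups that differ in unrelated ways would also fall below that range. The covariance therefore does not show a return towards control. No simulation called more than 1 gene in opposite directions in both comparisons. Independent lists of these lengths would share 298.4 genes higher then lower and 1295 lower then higher. Part of the excess may come from the shared LPS libraries, which are too few to be split.

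The genes with the strongest increases under LPS were partly lower in the extract group. Of the 27 genes at least 8-fold higher with LPS, 25 were lower in extract than in LPS cells, and 21 of these were still above control. None of the 27 was higher in extract than in LPS cells past the threshold. The 27 genes, like the 2-fold sets below, were chosen for extreme values in the LPS libraries used again here. That choice alone favours extract values on the control side of LPS, so these counts do not by themselves show a return. Their median log2 fold change was 3.66 in LPS versus control and 2.22 in extract versus control. Of the 157 genes at least 2-fold higher with LPS, 121 were lower in extract than in LPS cells and 8 were higher. Among those 121 genes, 76 were still above control, 33 did not differ from control past the threshold and 12 were below it. The 157 genes had a median log2 fold change of 1.73 in LPS versus control and 0.85 in extract versus control. Of the 151 genes at least 2-fold lower with LPS, 96 were higher in extract than in LPS cells and 15 were lower still, with medians of -1.27 in LPS and -0.77 in extract cells against control. The number of genes past a fold threshold moved with the pseudocount. At least 2-fold higher with LPS were 98 genes with a pseudocount of 5, of which 79 were lower in extract than in LPS cells. At least 2-fold lower were 54 genes with a pseudocount of 5 and 229 with 0.1, of which 31 and 152 were higher in extract than in LPS cells, and 99 with a filter of 5 TPM. Likewise, 12 genes were at least 8-fold higher with a pseudocount of 5 and 51 with a pseudocount of 0.1, of which 11 and 41 were lower in extract than in LPS cells.

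**Figure D3:**
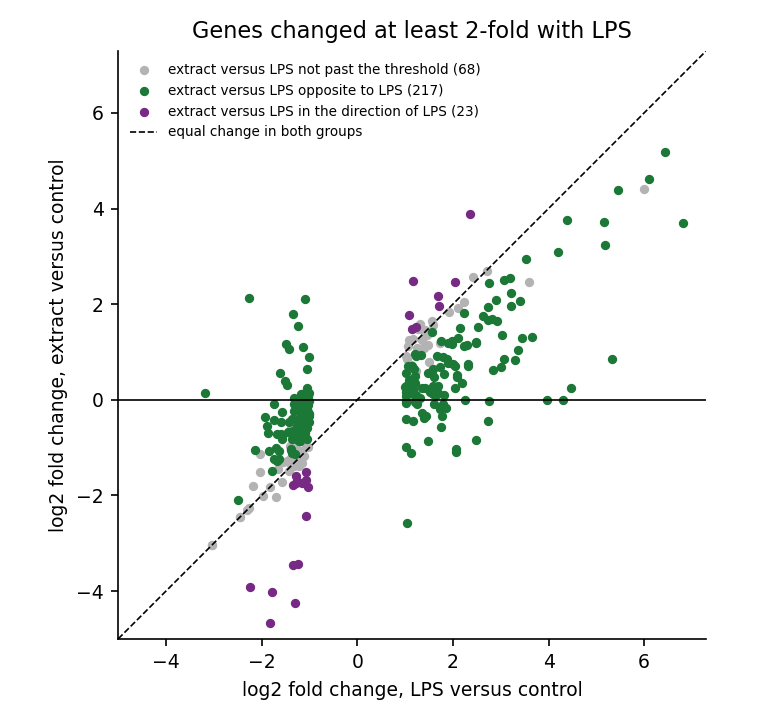
Log2 fold change in LPS versus control (horizontal axis) against that in extract versus control (vertical axis) for the 308 genes changed at least 2-fold with LPS; each point is a gene, coloured by its call in extract versus LPS. Of these, 217 moved opposite to the LPS change, 23 moved further in its direction and 68 did not pass the threshold; points on the dashed line changed equally in both groups.

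Extract versus control addressed how far the extract group stood from control cells. It gave 2716 genes that were higher and 3582 that were lower, with 155 and 226 of them changed at least 2-fold. The excess of lower genes depended on the scaling, with 3202 genes higher and 3084 lower after rescaling, and 3133 and 3141 with quantile normalization. The typical log2 difference was 0.418 ± 0.013 (jackknife SE) between extract and control, 0.394 ± 0.020 between LPS and control and 0.451 ± 0.019 between extract and LPS. The differences between these values were not tested. The slope of the extract-control changes on the LPS-control changes was 0.409 ± 0.056 over all tested genes. It follows by calculation from the typical differences and is not a separate result. The correction removes the noise of the shared control libraries, so LPS-control and extract-control changes unrelated to each other would give no clear slope. A deviation of the control group itself enters both changes, though, and would also give a positive slope. The slope therefore does not measure how much of the LPS response was kept. Genes in which one group stood apart from both others in the same direction were counted for each group. The extract group stood apart in 4565 genes, 2237 of them higher and 2328 lower, or 2409 and 2332 after rescaling. Of these, 1054 higher and 1564 lower genes had no call in LPS versus control, or 1417 and 1435 after rescaling. The LPS group stood apart in 3326 genes, the same genes that were counted above as changed the opposite way, and the control group in 1722. After rescaling the numbers were 4741 for extract, 2998 for LPS and 1492 for control. With both differences at least 2-fold, the extract group stood apart in 158 genes, the control group in 128 and the LPS group in 114.

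At the level of transcripts, 19383 were tested. LPS versus control changed 4459 of them, extract versus LPS 7585 and extract versus control 6202.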

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

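The slope, the typical differences and the counts of genes with 1 group apart were chosen after seeing the data, with their alternatives. Every count of changed genes and transcripts past the adjusted p kept within 1.5 times its value under a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, the fit of only the groups compared, no trend, library weights, and leaving out any library, wherever that alternative was planned for it. The exceptions came from scaling and from the fold threshold. In LPS versus control, higher genes went from 1193 to 2102 with median-of-ratios scaling and 1940 with quantile normalization, and lower genes from 3769 to 2278 and 2402. Requiring a 2-fold change left 157 higher and 151 lower genes in LPS versus control, 303 and 250 in extract versus LPS, 155 and 226 in extract versus control, 114 genes opposite and 9 in the same direction in the first 2 comparisons, 128 with the control group apart and 158 with the extract group apart, because fewer genes can pass. The slope of the extract-control on the LPS-control changes was 0.409 and moved past its standard error with a pseudocount of 0.1, to 0.496; the cause was not tested. The typical differences moved with the pseudocount (0.507 at 0.1 and 0.361 at 5 in extract versus LPS) and without a filter (0.368), and that of extract versus control moved without control replicate 1 (0.432). The excess of lower genes in extract versus control (2716 higher, 3582 lower) was not kept with median-of-ratios scaling (3202 and 3084) or quantile normalization (3133 and 3141), both of which centre the libraries. The fold changes of the 4 identifiers kept their direction and call under all alternatives run, except the small LPS-control difference of ENSRNOG00000002331, with an adjusted p of 0.0643 and 0.0711 under the 2 scalings. With the replicate block the counts of genes and transcripts past the adjusted p stayed within 1.5 times. Among them were 1105 higher and 3553 lower in LPS versus control, 4099 and 2973 in extract versus LPS, and 3141 opposite. The counts of genes with a transcript share change fell from 56, 16 and 26 to 17, 4 and 10. Of the 9 libraries, 6 deviated most like a library of their own number, but these 6 are mutual pairs. Deviations of same-numbered libraries correlated at 0.095 at most, and those of differently numbered libraries of different groups reached 0.089. The data therefore do not show a pairing by number. The gene list alternatives were not run, since no identifier was paired with a name. Without read depth, whether an uncalled low gene lacked a change or lacked reads was not examined.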

Other observations

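The tests of the transcript shares, the comparison with simulated unchanged groups, the count of genes changed in opposite ways after rescaling and the summed TPM of all genes called higher were chosen after the gene-level results were seen; the other tests below were set before their results. Relative use of transcripts was compared within genes. Of 4082 genes with transcript shares to compare, 56 had a transcript whose share shifted by at least 10 points between LPS and control (limma, adjusted p below 0.05), 16 between extract and LPS and 26 between extract and control. The median shift of the called transcripts was 25.4 points in LPS versus control, and 21 of the 56 genes were not called at the gene level. Over all 12192 genes tested in that comparison 40.7% were called, so most genes were uncalled there. On simulated shares a shift of 20 points was recovered in 67% of the changed transcripts, with 14 false calls, so an uncalled gene does not show an unchanged share. The count is fragile: leaving out a library other than control replicate 3 or extract replicate 3 brought the 56 genes down to between 12 and 36, and the replicate block gave 17, with 4 in extract versus LPS and 10 in extract versus control. The other comparisons ranged from 7 to 15 (extract versus LPS) and from 11 to 37 (extract versus control) with 1 library left out. Rerun with a minimum of 20 TPM per gene, the test gave 53, 22 and 21 genes. Only 34, 12 and 15 of the genes called at first had at least 20 TPM, so the rerun called other genes in part. With 10 splits of 6 libraries a share under 0.05 cannot be had: the real split, 1 of 10, gave 56 genes and the highest other 1 in LPS versus control, and 16 against 0 in extract versus LPS.

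The first pattern is the excess of lower over higher genes in LPS versus control. A candidate explanation is the composition of the TPM total: the 10 genes that gained most TPM went from 75980 to 111200, which lowers all other genes together by 0.056 on the log2 scale, against a median change of -0.084. With those 10 genes and the 10 that lost most removed and the rest rescaled, 68.4% of called genes were still lower, against 76%, so these genes account for part of the excess at most. All genes called higher rose together from 176900 to 241300 TPM, a log2 change of -0.118 for the summed rest. These genes were chosen because they rose in the same data and the total is fixed, so the rest had to fall. This sum therefore decides nothing, and composition through gains of many genes stays open. Rescaling by the median brings the excess to 52%, but centring forces this and decides nothing. A smaller amount of most transcripts per cell after LPS stays open, and TPM alone cannot tell it apart from gains spread over many genes.

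The second pattern is the set of genes changed by LPS and changed the opposite way in the extract group. Noise of the shared LPS libraries is argued against as the whole cause, since the covariance of the fold changes was -0.112 and the lowest of 100 simulations of unchanged groups -0.0322. Groups that differ in unrelated ways would pass this bound too, so it does not speak for a return towards control. Composition of the TPM total as the whole cause is argued against as well, since 2998 genes went opposite ways after rescaling and 3326 before. A part in the pattern stays open: among genes called in both comparisons, 86.7% went opposite ways after rescaling and 86.8% before, but the shared LPS group favours opposite signs there, so this share decides nothing. Of 100 splits of the 9 libraries into 3 groups, 3 gave as many genes as the real 3326, the real one included. Both others put the 3 extract libraries in the place of the LPS group: one exchanged the groups as a whole and gave 4565, and one mixed LPS and control libraries in the remaining groups and gave 3456. The share of 3 in 100 is under the bound of 0.05, but the count can be had without correct LPS and control labels. This test alone therefore does not exclude a chance split between LPS and control libraries as the source of the pattern. Both other splits count genes with the extract libraries apart, though, and do not speak for such a chance split. Against it, LPS versus control called 4962 genes, and the highest other split of those 6 libraries called 3. With 10 splits a share under 0.05 cannot be had, so these counts argue against it without excluding it. In number of calls, the extract group stands farther from the others than they stand from each other. The size of a return towards control was not measured, so this structure cannot be compared with it. What the extract does, and any difference in LPS exposure between the groups, which the labels do not give, stay open and untested.

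For the counts of changed genes, 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split, 1 of 10 each time, called 4962 genes in LPS versus control, 7240 in extract versus LPS and 6298 in extract versus control, and the highest of the other splits called 3, 1 and 1.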
